A study of Homo sapiens with 12 samples.

How the data were processed

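RNA of RCC4 cells was sequenced by the submitters as DNase-treated total RNA depleted of ribosomal RNA, on a NextSeq instrument. The 12 libraries covered VHL-negative and VHL-positive cells, each under DMSO or 5 µM JQ1, with 3 libraries per group. The labels do not describe the VHL construct, the time of treatment or whether replicates were separate cultures. The protocol also mentions cells with a short hairpin against MYC, which were not analysed here.

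The deposited table of raw values holds counts per Ensembl gene, for 60663 genes. The submitters' processing notes name STAR 2.7.8, Subread 2.0.3, featureCounts, DESeq2 1.30.1 and the build GRCh38, without giving their order; the strand setting is not given in the sources used here. In the authors' deposited tables of JQ1 against DMSO, 1 for each line, the fold change and its standard error are on the log2 scale. The unit of the authors' test statistic is a score, the fold change over its standard error. The authors' deposited tables also give a p-value and an adjusted p-value for each gene, as DESeq2 writes them. The mean over libraries in these deposited tables is of another (other) kind, counts divided by size factors.

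Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Library sizes were scaled by TMM, and genes were kept by edgeR's filter on low counts by group, which left 20714 genes holding 99.87% of counts. Of the deposited gene IDs, 60462 had a symbol and 201 had none, and 58395 were found in GENCODE release 29, which gave positions on GRCh38. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries. It gave JQ1 against DMSO in each line, VHL-negative against VHL-positive cells under each treatment, and the difference between both JQ1 effects. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM on TMM-scaled library sizes, and log2 CPM used a prior count of 2. The floor for folds was 3 counts.

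The tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Named genes were VHL, MYC and HILPDA always. To these were added the 6 largest rises and 6 largest falls among called genes with a mean of at least 4 log2 CPM, libraries that did not overlap between the groups and a symbol that is no placeholder. From each list up to 4 tested members with the smallest p were added. For the difference between JQ1 effects the 5 largest in each direction were named, without the condition on overlap. Sex-linked marker genes were left out. Some genes that this rule names are not reported here. Of 34 gene lists, 32 had at least 5 tested members. They were tested with limma's camera at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry.

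Alternatives were median-of-ratios size factors, total counts alone, other filters, DESeq2, limma-voom, fits of only the compared groups, a replicate block, removal of mitochondrial and structural RNA genes, stricter thresholds, and leaving out each library in turn. Added after seeing the data were fits without the third JQ1 library of both lines, fits without the first DMSO library of both lines, protein-coding genes only, and older symbols matched to the lists.

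Total counts per library, in replicate order, were 29029970, 30086128 and 24624980 (VHL-negative, DMSO), 30458147, 15452949 and 24383054 (VHL-negative, JQ1), 26532213, 26795635 and 32502310 (VHL-positive, DMSO) and 29669306, 27208308 and 18468751 (VHL-positive, JQ1). Tested on simulated data of this design, changes of 4-fold were recovered in at least 98.5% of genes. Changes of 2-fold were recovered in 73.1 to 80.6% of genes for the comparisons of 2 groups and in 32.8% for the difference, and changes of 1.5-fold in 17.9 to 26.9% and 1.49%. The simulation changed 66 or 67 genes per fold size, drawn from genes with higher counts, and left all others unchanged. Recovery may differ in the real data, where far more genes passed and many have lower counts. No spike-ins were used here, so changes in total RNA per cell are not measured. Markers of endothelial cells and leukocytes stayed at or below 10.7 CPM (ESAM) and 4.06 CPM (CSF1R) without TMM scaling in every library, and these lists had too few tested members for a test.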

Results

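RNA levels were measured in RCC4, a clear cell renal carcinoma cell line. The labels give the VHL-negative cells a loss of VHL, the tumour suppressor that directs hypoxia-inducible factors to degradation, and the VHL-positive cells its reintroduction into the same line. Each was treated with DMSO, the solvent control, or with 5 µM JQ1, a BET bromodomain inhibitor that the labels call a MYC inhibitor. The 12 libraries formed 4 groups of 3. The total count per library ran from 15452949 (VHL-negative, JQ1, replicate 2) to 32502310 (VHL-positive, DMSO, replicate 3). The duration of treatment is not stated in the labels, nor whether the replicates were separate cultures, so p-values may measure technical spread only. All values below have n = 3 libraries per group. Levels are CPM (TMM-scaled counts) with SD, and changes are log2 fold changes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 20714 genes.

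The series title concerns MYC, lipid droplets and HILPDA, so VHL, MYC and HILPDA were examined first. HILPDA (ENSG00000135245, GRCh38 chromosome 7, 128455849 to 128458418) encodes a lipid droplet protein that restrains lipolysis. In VHL-negative cells it rose 5.10-fold with JQ1, from 21.6 ± 3.79 to 110 ± 3.29 CPM (log2 2.35, SE 0.133, adjusted p = 1.23e-08), and all 3 treated libraries lay above all 3 controls. In VHL-positive cells HILPDA went from 6.28 ± 0.277 to 7.92 ± 0.311 CPM, which did not pass the threshold (log2 0.34, adjusted p = 0.0779). The difference between the lines passed it (log2 2.01, SE 0.19, adjusted p = 6.6e-05). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434), a transcription factor of growth and proliferation, fell in VHL-negative cells from 342 ± 84.4 to 160 ± 28.9 CPM (log2 -1.10, SE 0.209, adjusted p = 0.000869). In VHL-positive cells MYC measured 171 ± 48.0 CPM under DMSO and 161 ± 18.9 CPM under JQ1 (log2 -0.08, SE 0.207, adjusted p = 0.795), and without replicate 2 of the DMSO libraries the MYC change there was log2 0.16 (adjusted p = 0.613). For MYC the difference between the lines missed the threshold (log2 -1.01, adjusted p = 0.0852). It passed in DESeq2 (log2 -1.05, adjusted p = 0.0247) and in edgeR with no filter on low counts (log2 -1.06, adjusted p = 0.00158). These settings called 1283 and 1336 genes for the difference, against 250 in the reported fit. The MYC difference passed in 2 of the 12 fits that left out 1 library. These were without replicate 1 of the JQ1-treated VHL-negative libraries (log2 -1.17, adjusted p = 0.0194) and without replicate 2 of the DMSO-treated VHL-positive libraries (log2 -1.26, adjusted p = 0.0359). Over the 12 fits the MYC difference ran from log2 -1.26 to -0.81, with an adjusted p of up to 0.199.

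VHL (ENSG00000134086, chromosome 3, 10141008 to 10152220) rose 3.02-fold with JQ1 in VHL-positive cells, from 70.3 ± 7.62 to 212 ± 14 CPM (log2 1.59, SE 0.123, adjusted p = 3.47e-07). In VHL-negative cells it measured 26.4 ± 1.64 and 32.7 ± 2.39 CPM (log2 0.31, adjusted p = 0.0674). This rise of VHL passed with a filter of 1 CPM (log2 0.35, adjusted p = 0.0234) and with protein-coding genes only (log2 0.39, adjusted p = 0.0116). The difference between the lines passed the test (log2 -1.29, SE 0.173, adjusted p = 0.00161). Without the third JQ1 library of both lines, the difference for VHL had an adjusted p of 0.0694. Under DMSO, VHL-negative cells held less VHL RNA (log2 -1.41, adjusted p = 2.25e-07), more MYC RNA (log2 1.00, adjusted p = 0.00159) and more HILPDA RNA (log2 1.78, adjusted p = 4.51e-08) than VHL-positive cells. Under JQ1, HILPDA was 13.9-fold higher in VHL-negative cells (log2 3.79, SE 0.144, adjusted p = 1.41e-11) and VHL 6.49-fold lower (log2 -2.70, adjusted p = 1.49e-10), while MYC differed by log2 -0.01 (adjusted p = 0.974). The sign of this MYC value changed with total counts alone (log2 0.14), a filter of 1 CPM (log2 0.04) and protein-coding genes only (log2 0.10). It also changed without replicate 2 of the JQ1 libraries of VHL-negative (log2 0.12) or VHL-positive cells (log2 0.08).

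**Figure D1:**
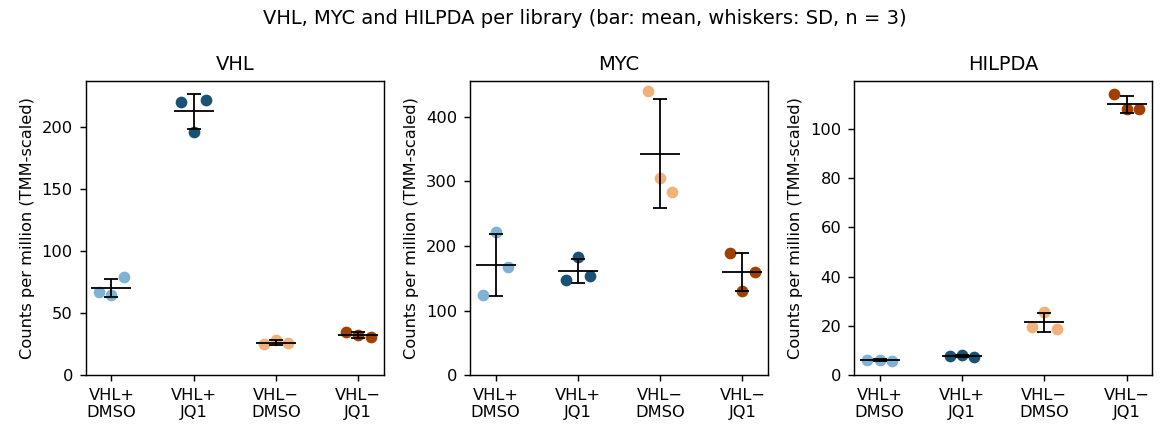
CPM of VHL, MYC and HILPDA in each of the 12 libraries (points), with the mean and SD of each group of 3. HILPDA reached 110 ± 3.29 in JQ1-treated VHL-negative cells, and VHL 212 ± 14 in JQ1-treated VHL-positive cells.

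What JQ1 changes in VHL-positive cells was asked next. Among moderately to highly expressed genes whose libraries did not overlap between the groups, the largest fall was that of TM4SF18 (ENSG00000163762, chromosome 3, 149318498 to 149334414), a tetraspanin-like membrane protein gene, which fell 13.6-fold from 151 ± 26.3 to 11.0 ± 1.44 CPM (log2 -3.77, SE 0.167, adjusted p = 1.27e-09). FLG, which encodes filaggrin, fell 8.57-fold from 70.3 ± 2.38 to 8.20 ± 1.3 CPM (log2 -3.10, SE 0.159). The secreted factors INHBA (an activin subunit) and IGFBP3 (a binding protein of insulin-like growth factors) each fell by 2.96 on the log2 scale, KCTD15 fell by 2.95 and TRIM55 fell by 2.87. The largest rise was that of TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), an inhibitor of thioredoxin and of glucose uptake, which rose 6.12-fold from 178 ± 72.0 to 1090 ± 88.4 CPM (log2 2.61, SE 0.261, adjusted p = 3.43e-06). UCA1, a long noncoding RNA (log2 2.29), TXNRD1, thioredoxin reductase (log2 2.27), FTL, ferritin light chain (log2 2.10), MCRIP1 (log2 2.06) and SERTAD1 (log2 2.05) followed. FTL went from 1080 ± 263 to 4630 ± 274 CPM. In all, 3167 genes rose and 3422 fell, 867 and 1771 of them at least 2-fold. With total counts alone 2069 rose and 3998 fell, so the share of rises was 34.1% instead of 48.1%. Without the third JQ1 library of both lines, 4160 genes passed instead of 6589.

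Genes of inflammation fell in VHL-positive cells: of 30 tested members of the NF-kB list, 22 fell, 0 rose and 8 did not pass (median log2 -1.0, list test adjusted p = 1.82e-06; adjusted p = 0.634 with an estimated correlation). Counts were 23 falling adjusted over the list alone. Its members included VCAM1, a leukocyte adhesion molecule (log2 -3.63, 199 ± 106 to 15.9 ± 1.19 CPM), LIF (log2 -1.04) and NFKB1, a subunit of NF-kB itself (log2 -1.0). Of 39 interferon-stimulated genes, 21 fell, 8 rose and 10 did not pass (median log2 -0.60, adjusted p = 0.00542; adjusted p = 0.64 with an estimated correlation). There were 23 falling and 9 rising adjusted over the list alone. IFI44L (log2 -3.92), GBP1 (log2 -3.48) and OAS1 (log2 -1.96) fell, while IRF7, a transcription factor of the interferon response, rose 3.96-fold (log2 1.99, SE 0.149). Of 23 renal epithelial markers, 11 fell, 2 rose and 10 did not pass (median log2 -0.61, adjusted p = 0.0045; adjusted p = 0.634 with an estimated correlation). These became 11 falling and 3 rising adjusted over the list alone. The kidney cadherins CDH16 (log2 -1.72) and CDH6 (log2 -1.29) were among them. Of the 46 DNA replication genes 21 fell, 1 rose and 24 did not pass (median log2 -0.49, adjusted p = 5.23e-05; adjusted p = 0.666 with an estimated correlation). The numbers were 26 falling and 1 rising adjusted over the list alone. They included E2F2 (log2 -2.85), MCM5, part of the replicative helicase (log2 -1.59), and CDT1, a licensing factor (log2 -1.32). Of 42 mitosis genes 12 fell, 0 rose and 30 did not pass (median log2 -0.37, adjusted p = 0.00425; adjusted p = 0.7 with an estimated correlation), with 12 falling adjusted over the list alone, among them FOXM1 (log2 -1.44) and MKI67 (log2 -1.12). Of 47 MYC target genes 17 fell, 2 rose and 28 did not pass (median log2 -0.29, adjusted p = 0.00694; adjusted p = 0.7 with an estimated correlation). Counts were 18 falling and 2 rising adjusted over the list alone. NME1 (log2 -1.35), PPRC1 (log2 -1.31) and DKC1 (log2 -0.81) fell. Without replicate 2 of the DMSO libraries the mitosis list (median log2 -0.17, adjusted p = 0.173) and the MYC targets (median log2 -0.17, adjusted p = 0.153) lost their calls and the replication median moved to log2 -0.25 (adjusted p = 0.00789). Without replicate 2 of the JQ1 libraries the mitosis list and the MYC targets each had an adjusted p of 0.0643. With fry the adjusted p was 0.102 for MYC targets, 0.122 for mitosis and 0.0561 for replication.

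Genes of lysosomes, glycolysis, the HIF pathway, fatty acid oxidation and cholesterol synthesis rose in VHL-positive cells. Of 36 lysosome and autophagy genes 17 rose, 4 fell and 15 did not pass (median log2 0.48, adjusted p = 0.00122; adjusted p = 0.634 with an estimated correlation). There were 20 rising and 4 falling adjusted over the list alone. The autophagy receptor SQSTM1 (log2 1.17) and the sialidase NEU1 (log2 1.17) rose, whereas TFEB, a transcription factor of lysosomal genes, fell (log2 -1.13). Of 22 glycolysis genes 12 rose, 0 fell and 10 did not pass (median log2 0.44, adjusted p = 0.0034; adjusted p = 0.64 with an estimated correlation), with 13 rising adjusted over the list alone. PKM, pyruvate kinase, went from 2750 ± 226 to 5140 ± 366 CPM (log2 0.90), and PDK3 rose as well (log2 0.93). Of 14 factors of the HIF pathway 8 rose, 0 fell and 6 did not pass (median log2 0.46, adjusted p = 0.00425; adjusted p = 0.634 with an estimated correlation), also 8 adjusted over the list alone. Besides VHL they included HIF1A (log2 0.64) and EPAS1, which encodes HIF-2alpha (log2 0.76). Of 26 fatty acid oxidation genes 13 rose, 1 fell and 12 did not pass (median log2 0.37, adjusted p = 0.00842; adjusted p = 0.64 with an estimated correlation), with 13 rising and 1 falling adjusted over the list alone. ETFDH rose (log2 1.5). Of 24 cholesterol synthesis genes 9 rose, 0 fell and 15 did not pass (median log2 0.27, adjusted p = 0.00542; adjusted p = 0.64 with an estimated correlation), with 10 rising adjusted over the list alone, TM7SF2 (log2 1.80) and IDI1 (log2 0.85) among them. Of 54 cytosolic ribosomal protein genes 6 rose, 1 fell and 47 did not pass (median log2 0.25, adjusted p = 0.0407; adjusted p = 0.873 with an estimated correlation). These became 1 rising and 0 falling adjusted over the list alone. The ribosomal call was lost without replicate 2 of the DMSO libraries (adjusted p = 0.0932) or replicate 1 of the JQ1 libraries (adjusted p = 0.0858). It was also lost with a filter of 1 CPM (adjusted p = 0.0834), with DESeq2 (0.0774), with fry (0.439) and with protein-coding genes only (0.101). The lipid droplet list as a whole did not pass (3 rose, 2 fell and 8 did not pass, with 3 and 2 adjusted over the list alone; median log2 -0.01, adjusted p = 0.95), although the triglyceride-forming enzyme DGAT1 (log2 1.60, 24.0 ± 4.10 to 72.6 ± 4.68 CPM) and the lipase PNPLA2 (log2 1.42), which are on other lists, rose. The lipolysis list that holds PNPLA2 did not pass the list test (median log2 0.14, adjusted p = 0.211) but passed with fry (0.00338). Members of the triglyceride synthesis list moved both ways. AGPAT3 measured 102 to 123 CPM under DMSO and 62 to 64 CPM under JQ1, whereas GPAT4 measured 65.8 to 69.2 and 95.7 to 106 CPM.

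In VHL-negative cells JQ1 gave falls of up to 20.7-fold among the same class of well expressed genes. TM4SF18 fell from 80.6 ± 7.70 to 3.85 ± 0.576 CPM (log2 -4.37, SE 0.178, adjusted p = 3.98e-10), INHBA from 219 ± 22.3 to 18.6 ± 2.49 CPM (log2 -3.55, SE 0.243), and GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), a stress-induced cytokine, from 181 ± 7.93 to 18.5 ± 0.0576 CPM (log2 -3.29, SE 0.127, adjusted p = 3.37e-10). TRIM55 (log2 -3.59), the transcription factor ATOH8 (log2 -3.15) and the efflux transporter ABCC2 (log2 -3.10) were the other large falls. CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373), a matricellular growth factor, rose 7.83-fold from 37.8 ± 7.98 to 296 ± 31.1 CPM (log2 2.97, SE 0.274, adjusted p = 1.12e-06). NEAT1, a nuclear noncoding RNA, rose from 1730 ± 1040 to 11000 ± 6060 CPM (log2 2.67, SE 0.491), IRF7 from 7.91 ± 0.676 to 43.7 ± 2.16 CPM (log2 2.46), and TXNIP from 306 ± 29 to 1510 ± 382 CPM (log2 2.30). ALDOA also rose (log2 2.36), but 53.5% of its exon length overlaps other annotated genes, which leaves its counts uncertain. In all, 3032 genes rose and 3617 fell, 1414 and 1482 of them at least 2-fold (2471 and 3670 with total counts alone), and without the third JQ1 library of both lines 3957 genes passed instead of 6649.

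The gene lists showed falls in MYC target, inflammation and matrix genes of VHL-negative cells. DNA replication (4 rose, 5 fell and 37 did not pass, 3 and 4 adjusted over the list alone; median log2 -0.02, adjusted p = 0.671) and mitosis (0 rose, 4 fell and 38 did not pass, 0 and 0 adjusted over the list alone; median log2 -0.15, adjusted p = 0.271) did not pass there. The mitosis list passed without replicate 1 of the JQ1 libraries (median log2 -0.26, adjusted p = 0.0439) and with no filter on low counts (median log2 -0.20, adjusted p = 0.00971). Its difference between the lines missed the threshold (median log2 0.18, adjusted p = 0.0671) but passed in 10 other settings, with adjusted p from 0.000222 to 0.0323. Of 47 MYC target genes 20 fell, 2 rose and 25 did not pass (median log2 -0.48, adjusted p = 2e-04; adjusted p = 0.824 with an estimated correlation), with 25 falling and 2 rising adjusted over the list alone. NME1 (log2 -1.32) and GART, an enzyme of purine synthesis (log2 -0.78), fell. Of 30 NF-kB list genes 15 fell, 0 rose and 15 did not pass (median log2 -0.70, adjusted p = 0.000461; adjusted p = 0.824 with an estimated correlation), also 15 adjusted over the list alone, CSF1 (log2 -1.3) and NFKB1 (log2 -0.96) among them. Of 37 matrix and mesenchymal genes 16 fell, 3 rose and 18 did not pass (median log2 -0.38, adjusted p = 0.0247; adjusted p = 0.824 with an estimated correlation). The numbers were 18 falling and 3 rising adjusted over the list alone. FN1, fibronectin, went from 3000 ± 270 to 822 ± 123 CPM (log2 -1.86), and THBS1 (log2 -1.53) and the protease MMP14 (log2 -1.07) fell too. Of 39 interferon-stimulated genes 13 fell, 1 rose (IRF7) and 25 did not pass (median log2 -0.16, adjusted p = 0.0247; adjusted p = 0.824 with an estimated correlation), with 13 and 1 adjusted over the list alone. IFI44L (log2 -3.60) and the immunoproteasome subunit PSMB8 (log2 -2.11) fell. Of 23 renal epithelial markers 9 fell, 2 rose and 12 did not pass (median log2 -0.47, adjusted p = 0.027; adjusted p = 0.824 with an estimated correlation). Counts were 9 falling and 3 rising adjusted over the list alone, with CDH16 (log2 -1.84) and the injury marker HAVCR1 (log2 -1.27) falling. Of 27 genes of the ATF4 and unfolded protein response 8 fell, 0 rose and 19 did not pass (median log2 -0.35, adjusted p = 0.027; adjusted p = 0.824 with an estimated correlation), also 8 adjusted over the list alone, XBP1 (log2 -1.18) and TRIB3 (log2 -0.70) among them. Of 54 nuclear genes of oxidative phosphorylation 13 fell, 1 rose and 40 did not pass (median log2 -0.31, adjusted p = 0.000915; adjusted p = 0.824 with an estimated correlation), with 13 and 1 adjusted over the list alone, and NDUFA9 fell (log2 -1.07). Of 54 ribosomal protein genes 11 fell, 0 rose and 43 did not pass (median log2 -0.37, adjusted p = 0.00133; adjusted p = 0.832 with an estimated correlation). There 0 passed adjusted over the list alone.

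Fewer lists rose in VHL-negative cells. Of 16 genes fixed as responders to BET inhibitors 9 rose, 2 fell and 5 did not pass (median log2 1.07, adjusted p = 0.0247; adjusted p = 0.561 with an estimated correlation). There were 10 rising and 3 falling adjusted over the list alone. HEXIM1, an inhibitor of the elongation factor P-TEFb, went from 67.7 ± 3.67 to 182 ± 4.57 CPM (log2 1.43), ZCCHC24 rose (log2 1.42), and IL7R fell from 14.3 ± 1.78 to 0.563 ± 0.185 CPM (log2 -4.66). In VHL-positive cells this list did not pass (7 rose, 4 fell and 5 did not pass, also 7 and 4 adjusted over the list alone; median log2 0.25, adjusted p = 0.0912), and neither did its difference between the lines (adjusted p = 0.354). The list passed in VHL-positive cells with DESeq2 (0.00927), no filter on low counts (0.0205), fry (0.000332), members on 1 list only (0.0225) and without replicate 2 of the DMSO libraries (0.0408). The list test asks for a shift in 1 direction, so rising and falling members offset each other. In VHL-positive cells HEXIM1 measured 75.3 to 99.5 CPM under DMSO and 208 to 226 CPM under JQ1. IL7R measured 1.32 to 1.38 CPM there under DMSO and 0.0728 to 0.405 CPM under JQ1. Of 22 glycolysis genes 11 rose, 2 fell and 9 did not pass (median log2 0.40, adjusted p = 0.0247; adjusted p = 0.824 with an estimated correlation). These became 11 rising and 3 falling adjusted over the list alone, with GAPDH (log2 1.46) and LDHA (log2 1.09) rising. On the lipid droplet list, which did not pass as a whole (2 rose, 5 fell and 6 did not pass, 4 and 5 adjusted over the list alone; median log2 -0.22, adjusted p = 0.469), HILPDA rose while PLIN2, a coat protein of lipid droplets, went from 171 ± 33.9 to 90.4 ± 25.8 CPM (log2 -0.92, adjusted p = 0.00118) and CAV1 fell (log2 -0.77). DGAT1 (log2 1.55) and PNPLA2 (log2 1.54) rose here too, and the monoglyceride lipase MGLL fell (log2 -1.03). The triglyceride synthesis list that holds DGAT1 had a negative median and did not pass (median log2 -0.33, list test adjusted p = 0.184). With no filter on low counts this list passed as falling (median log2 -0.37, adjusted p = 0.0238). The lipolysis list that holds PNPLA2 and MGLL did not pass the list test either (median log2 -0.18, adjusted p = 0.633) but passed with fry (0.0394).

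Several list results in VHL-negative cells rested on single libraries. Without replicate 2 of the JQ1 libraries the calls of oxidative phosphorylation (median log2 -0.15, adjusted p = 0.0779), ribosomal proteins (median log2 -0.18, adjusted p = 0.116), interferon-stimulated genes (adjusted p = 0.0779) and the ATF4 list (median log2 -0.22, adjusted p = 0.121) were lost. Without replicate 1 of the JQ1 libraries glycolysis lost its call (median log2 0.23, adjusted p = 0.135), and the medians were log2 -0.64 for ribosomal proteins, -0.57 for oxidative phosphorylation, -0.32 for interferon-stimulated genes and -0.27 for renal markers. The interferon median was log2 -0.07 without replicate 3 of the JQ1 libraries. Without replicate 1 of the DMSO libraries it was log2 -0.05, with log2 -0.24 for matrix genes and -0.27 for renal markers. Library composition moved with this group as well: the JQ1-treated VHL-negative libraries 1, 2 and 3 held 2.92, 6.24 and 4.68% of counts in noncoding and pseudogene RNA and 1.04, 2.18 and 1.64% in MALAT1. The 3 DMSO libraries of that line held 1.58, 2.52 and 2.11% in noncoding and pseudogene RNA, and 0.221, 0.483 and 0.318% in MALAT1. In VHL-positive cells MALAT1 took 0.673, 0.198 and 0.326% under DMSO and 0.784, 0.829 and 0.757% under JQ1, and the signal recognition particle RNA gene RN7SL1 took 1.97, 0.247 and 0.537% under DMSO and 1.52, 1.01 and 1.22% under JQ1. The list of nuclear and structural RNAs, fixed as a measure of RNA quality, did not pass for JQ1 in VHL-positive cells (2 rose, 0 fell and 8 did not pass, also 2 and 0 adjusted over the list alone; median log2 0.34, adjusted p = 0.203). It passed there without replicate 1 of the DMSO libraries (median log2 1.74, adjusted p = 0.0371), without the first DMSO library of both lines (0.0241) and with no filter on low counts (0.046). In VHL-negative cells 4 rose, 0 fell and 6 did not pass (also 4 and 0 adjusted over the list alone; median log2 0.46, adjusted p = 0.0864). There it passed with no filter on low counts (0.0314) and with fry (0.0394). Without mitochondrial and structural RNA genes, a setting that removed members of this list itself, the reduced list passed (median log2 0.75, adjusted p = 0.042). The first VHL-negative DMSO library held 20.1% of counts in mitochondrial ribosomal RNA and 5.24% in mitochondrial messenger RNA, against 11 and 8.76%, and 2.08 and 1.13%, in the second and the third. The list of 13 mitochondrially encoded genes did not pass for JQ1 in VHL-negative cells (0 rose, 0 fell and 13 did not pass, also 0 and 0 adjusted over the list alone; median log2 -0.11, adjusted p = 0.676). Without that library its median was log2 0.82 (adjusted p = 0.0022). Likewise its median moved from log2 0.27 (0.931) to -0.75 (0.022) for the lines under DMSO and from log2 -0.20 (0.734) to 0.88 (0.000853) for the difference between JQ1 effects. With protein-coding genes only, the calls of the ATF4 list (adjusted p = 0.119), interferon-stimulated genes (0.111), renal markers (0.111) and matrix genes (0.0836) were lost. With a filter of 1 CPM the ATF4 list (0.0724) and matrix genes (0.0708) lost theirs. In fits of only the compared groups the ATF4 list and interferon-stimulated genes each had 0.0544, and the ATF4 list had 0.0585 with members on 1 list only. With fry, ribosomal proteins had 0.163 and oxidative phosphorylation 0.116.

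**Figure D2:**
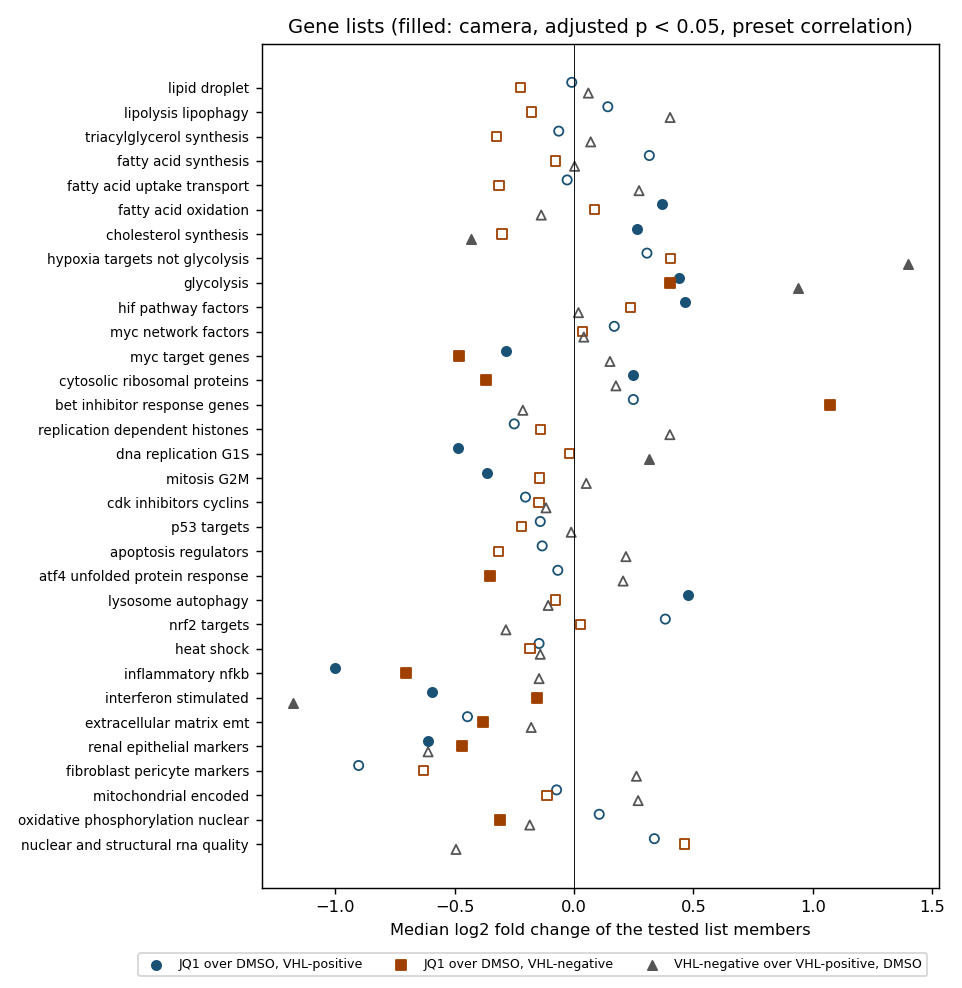
Median log2 fold change of each of the 32 tested gene lists for JQ1 in VHL-positive cells, JQ1 in VHL-negative cells, and VHL-negative against VHL-positive cells under DMSO. Filled points mark a list test adjusted p under 0.05 with the preset correlation; the hypoxia list lies at log2 1.40 between the lines under DMSO.

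How far the response to JQ1 was common to both lines was asked with 2 comparisons that share no library. Of the genes tested, 1550 rose and 2012 fell in both lines, against 464 and 598 for independent calls, and 17 and 28 passed in opposite directions, against 553 and 501. Among called genes with a mean of at least 4 log2 CPM and libraries that did not overlap, TM4SF18, INHBA and TRIM55 were in the 6 largest falls and TXNIP in the 6 largest rises of both lines. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated with Pearson's r = 0.586 and Spearman's rho = 0.506. Without the third JQ1 library of both lines the genes shared in direction numbered 2083 instead of 3562.

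**Figure D3:**
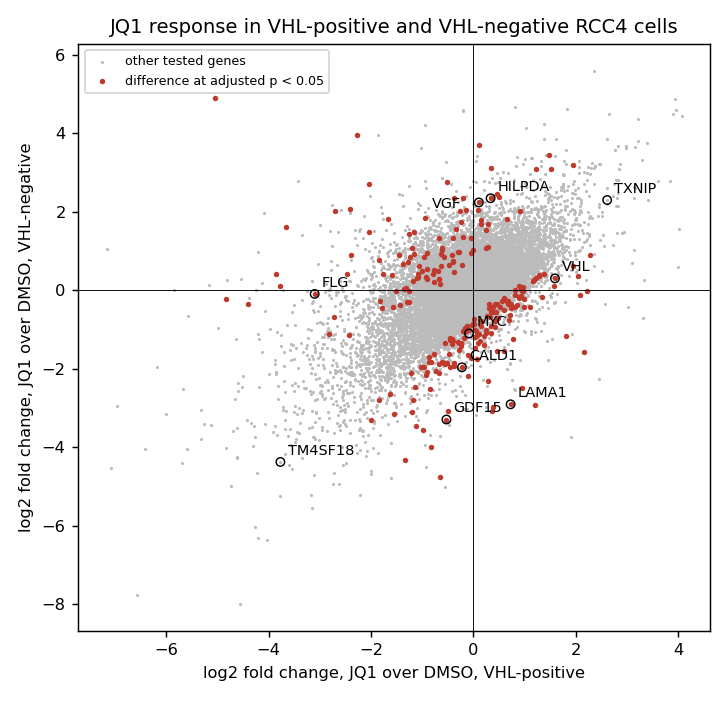
Log2 fold change by JQ1 of each tested gene in VHL-positive cells (horizontal) and VHL-negative cells (vertical). Red points are the 250 genes whose change differed between the lines at adjusted p under 0.05, and 10 genes, among them genes that did not pass, are circled and labelled.

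Hypoxia targets outside glycolysis moved both ways under JQ1. In VHL-positive cells 16 of 38 rose, 6 fell and 16 did not pass (17 and 7 adjusted over the list alone; median log2 0.30, adjusted p = 0.0736). There the list passed with total counts alone (0.048), no filter on low counts (0.00407), without replicate 2 of the DMSO libraries (0.0408), replicate 3 of the JQ1 libraries (0.0206) or the third JQ1 library of both lines (0.0209). In VHL-negative cells 16 rose, 5 fell and 17 did not pass (18 and 6 adjusted over the list alone; median log2 0.41, adjusted p = 0.0642). In VHL-negative cells the list passed when HILPDA was counted on it through its older symbol, a choice made after its values were seen (adjusted p = 0.0255). It passed there too with members on 1 list only (adjusted p = 0.0277), a filter of 1 CPM (0.0432), protein-coding genes only (0.0224) or without the first DMSO library of both lines (0.0462). Without replicate 1 of the DMSO libraries its adjusted p was 0.049, and without replicate 2 of the JQ1 libraries 0.0212. ADM rose in both lines (log2 1.38 in VHL-positive and 1.87 in VHL-negative cells), whereas IGFBP3 (log2 -2.96 and -2.64) and LOX, a collagen cross-linking enzyme (log2 -1.82 and -1.62), fell in both.

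VHL-negative and VHL-positive cells under DMSO were compared to describe the lines without drug. The largest excesses in VHL-negative cells included targets of hypoxia-inducible factors. Their list as a whole, whose call was lost with an estimated correlation, is given in the next paragraph. Among called genes with a mean of at least 4 log2 CPM and libraries that did not overlap, NDUFA4L2 (ENSG00000185633, chromosome 12, 57234903 to 57240715), a mitochondrial protein gene induced by hypoxia, was 126-fold higher at 246 ± 91.2 against 1.94 ± 0.522 CPM (log2 6.98, SE 0.364, adjusted p = 3.81e-10), and ADM, the vasodilator adrenomedullin, was 24.1-fold higher (log2 4.59, SE 0.161). The peptidase MME (log2 4.46), the adhesion molecule L1CAM (log2 4.21), PPFIA4 (log2 4.12) and the insulin receptor substrate IRS2 (log2 3.58) were the other large excesses of that class. CHST9 (log2 -5.78, SE 0.22, 213 ± 34.3 against 3.88 ± 0.836 CPM), the laminin chain LAMA1 (log2 -3.61), MAL2 (log2 -4.62), STON2 (log2 -3.91) and CDH16 (log2 -3.61) were lower. In all, 3058 genes were higher and 3299 lower in VHL-negative cells, 1204 and 1842 of them at least 2-fold. With total counts alone 3338 were higher and 2741 lower, which turned the balance (54.9% higher instead of 48.1%).

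Of 38 hypoxia targets outside glycolysis, 31 were higher in VHL-negative cells under DMSO, 1 was lower and 6 did not pass (median log2 1.40, adjusted p = 6.52e-18; adjusted p = 0.134 with an estimated correlation). The numbers were 34 higher and 1 lower adjusted over the list alone. They included the glucose transporter SLC2A3 (log2 4.97), the prolyl hydroxylase EGLN3 (log2 4.57, 29.7 ± 0.759 against 1.24 ± 0.0532 CPM) and PFKFB4 (log2 3.13). HIF1A itself was lower (log2 -2.31, 127 ± 11.6 against 630 ± 22.5 CPM), as was EPAS1 (log2 -0.70). Of 22 glycolysis genes 16 were higher, 2 lower and 4 did not pass (median log2 0.94, adjusted p = 5.99e-09; adjusted p = 0.366 with an estimated correlation). Counts were 18 higher and 2 lower adjusted over the list alone. The lactate transporter SLC16A3 (log2 3.05) and the pyruvate dehydrogenase kinases PDK3 (log2 2.97) and PDK1 (log2 2.36) led them. Of 39 interferon-stimulated genes 30 were lower, 0 higher and 9 did not pass (median log2 -1.18, adjusted p = 8.42e-12; adjusted p = 0.161 with an estimated correlation). There were 31 lower and 1 higher adjusted over the list alone, with OAS1 (log2 -3.05) and PSMB9 (log2 -2.18) as examples. Of 24 cholesterol synthesis genes 13 were lower, 1 higher and 10 did not pass (median log2 -0.43, adjusted p = 0.00189; adjusted p = 0.961 with an estimated correlation). These became 14 lower and 1 higher adjusted over the list alone, among them HMGCS1 (log2 -1.14) and MVD (log2 -1.0). Of 46 DNA replication genes 9 were higher, 1 lower and 36 did not pass (median log2 0.31, adjusted p = 0.0101; adjusted p = 0.961 with an estimated correlation), with 9 and 1 adjusted over the list alone, POLA1 (log2 1.15) among them. Without VHL-positive DMSO replicate 1 the replication call was lost (median log2 0.14, adjusted p = 0.405), and without replicate 2 the median was log2 0.54. The call was also lost with DESeq2 (adjusted p = 0.0751), with fry (0.322) and without the first DMSO library of both lines (median log2 0.12, 0.51). That replicate 1 library had counts in 39651 genes against 29341 to 34456 in the other 11. Complement C3 was lower in VHL-negative cells (log2 -3.23, 120 ± 17.3 against 1130 ± 118 CPM) and the lipid droplet list did not differ as a whole (3 higher, 2 lower and 8 not passing, also 3 and 2 adjusted over the list alone; adjusted p = 0.785), its median being log2 0.06 and its mean log2 -0.21.

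Under JQ1 the lines differed in 8479 genes, 4082 higher and 4397 lower in VHL-negative cells, 2385 and 1752 of them at least 2-fold; the count was 4814 without the third JQ1 library of both lines. With total counts alone 5152 were higher and 3148 lower, again turning the balance (62.1% higher instead of 48.1%). Of 38 hypoxia targets 31 were higher, 2 lower and 5 did not pass (median log2 1.16, adjusted p = 7.2e-13; adjusted p = 0.32 with an estimated correlation). The numbers were 31 higher and 3 lower adjusted over the list alone. Of 22 glycolysis genes 15 were higher, 2 lower and 5 did not pass (median log2 1.01, adjusted p = 2.38e-06; adjusted p = 0.459 with an estimated correlation), with 15 and 2 adjusted over the list alone. Of 46 DNA replication genes 34 were higher, 0 lower and 12 did not pass (median log2 0.74, adjusted p = 1.4e-08; adjusted p = 0.66 with an estimated correlation), with 37 higher adjusted over the list alone. Lower lists were cholesterol synthesis (19 lower, 0 higher and 5 not passing, 20 lower adjusted over the list alone; median log2 -1.12, adjusted p = 6.75e-09; adjusted p = 0.459 with an estimated correlation) and interferon-stimulated genes (26 lower, 0 higher and 13 not passing, 26 adjusted over the list alone; median log2 -1.07, adjusted p = 6.75e-09; adjusted p = 0.342 with an estimated correlation). Oxidative phosphorylation (34 lower, 0 higher and 20 not passing, 35 adjusted over the list alone; median log2 -0.62, adjusted p = 6.75e-09; adjusted p = 0.6 with an estimated correlation) and ribosomal proteins (21 lower, 0 higher and 33 not passing, 21 adjusted over the list alone; median log2 -0.43, adjusted p = 0.000131; adjusted p = 0.874 with an estimated correlation) were lower too. So were fatty acid oxidation (17 lower, 3 higher and 6 not passing, 19 and 3 adjusted over the list alone; median log2 -0.67, adjusted p = 0.000426; adjusted p = 0.529 with an estimated correlation) and the lysosome list (18 lower, 4 higher and 14 not passing, 18 and 4 adjusted over the list alone; median log2 -0.39, adjusted p = 0.00133; adjusted p = 0.529 with an estimated correlation). NRF2 targets (9 lower, 1 higher and 11 not passing, 11 and 1 adjusted over the list alone; median log2 -0.55, adjusted p = 0.00133; adjusted p = 0.529 with an estimated correlation) and renal markers (8 lower, 2 higher and 13 not passing, 8 and 2 adjusted over the list alone; median log2 -0.56, adjusted p = 0.0212; adjusted p = 0.459 with an estimated correlation) completed them. The ribosomal median was log2 -0.70 without replicate 1 of the JQ1-treated VHL-negative libraries and log2 -0.23 without replicate 2, and the NRF2 median was log2 -0.34 without replicate 2. Renal markers lost their call with members on 1 list only (adjusted p = 0.0589) and with protein-coding genes only (0.103), and ribosomal proteins with fry (0.0627).

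Whether JQ1 acted differently in the lines was tested as the JQ1 change in VHL-negative cells minus that in VHL-positive cells. The genes that parted most included LAMA1, a laminin chain of basement membranes, which rose in VHL-positive cells from 91.6 ± 8.39 to 152 ± 15.9 CPM and fell in VHL-negative cells from 7.51 ± 0.779 to 1.03 ± 0.244 CPM (difference log2 -3.63, SE 0.23, adjusted p = 3.66e-07). GDF15 fell in both lines but to 127 ± 14.1 CPM in VHL-positive and 18.5 ± 0.0576 CPM in VHL-negative cells (difference log2 -2.76, SE 0.167, adjusted p = 3.44e-07). FLG fell in VHL-positive cells while measuring 69.1 ± 10.6 and 65.0 ± 7.87 CPM in VHL-negative cells (difference log2 3.01, SE 0.211, adjusted p = 1.12e-06). CALD1, a regulator of actin and myosin (log2 -1.74), CP, ceruloplasmin (log2 -1.67), and CRISPLD2 (log2 -1.61) had the more negative change in VHL-negative cells. VGF, a secreted neuropeptide precursor (log2 2.13), BAHCC1 (log2 1.96) and HILPDA (log2 2.01) had the more positive one. These 9 genes passed in all 12 fits that left out 1 library, and 8 of them without the third JQ1 library of both lines, BAHCC1 then having an adjusted p of 0.101. NFIC (log2 2.03, adjusted p = 0.0489) passed in 1 of those 12 fits, and leaving out any of the other 11 libraries ended its call, with an adjusted p of up to 0.144. Its call was also lost with limma-voom (0.084), a filter of 1 CPM (0.0515), a replicate block (0.0529), and without the third JQ1 (0.271) or the first DMSO library (0.0539) of both lines.

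In total 250 genes passed for the difference, 103 positive and 147 negative, 94 and 92 of them at least 2-fold, and this count depended strongly on single libraries. With total counts alone 112 were positive and 87 negative, so most differences were then positive (56.3% instead of 41.2%). The count was 3510 without replicate 1 and 43 without replicate 3 of the JQ1-treated VHL-negative libraries, and 103 without replicate 2. Without replicates 1, 2 or 3 of the other groups it was 147, 165 and 124 (VHL-negative, DMSO), 55, 62 and 82 (VHL-positive, JQ1), and 203, 345 and 142 (VHL-positive, DMSO). DESeq2 called 1283 genes, and 4657 had an unadjusted p under 0.05 in edgeR.

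Among the lists, the ribosomal protein genes differed in their response (median log2 -0.58, adjusted p = 5.09e-08; adjusted p = 0.623 with an estimated correlation), as did oxidative phosphorylation (median log2 -0.48, adjusted p = 2.26e-07; adjusted p = 0.623 with an estimated correlation), although none of the 54 genes of either list passed by itself in edgeR, also adjusted over the list alone. Cholesterol synthesis (median log2 -0.60, adjusted p = 5.94e-07; adjusted p = 0.623 with an estimated correlation) had 2 genes with a negative difference, 0 positive and 22 not passing, and 14 negative adjusted over the list alone. The sterol regulator INSIG1 was one of them (log2 -1.06, adjusted p = 0.017). DNA replication (median log2 0.43, adjusted p = 8.3e-06; adjusted p = 0.676 with an estimated correlation) had 2 positive, 0 negative and 44 not passing, with 9 positive adjusted over the list alone. The lysosome list (median log2 -0.36, adjusted p = 0.000226; adjusted p = 0.623 with an estimated correlation) had 0 passing of 36, with 3 negative adjusted over the list alone, and fatty acid oxidation (median log2 -0.36, adjusted p = 0.0107; adjusted p = 0.623 with an estimated correlation) had 0 of 26, also adjusted over the list alone. NRF2 targets (median log2 -0.35, adjusted p = 0.0107; adjusted p = 0.623 with an estimated correlation) had 1 negative, 0 positive and 20 not passing, with 4 negative adjusted over the list alone. TXNRD1 was the one that passed (log2 -1.37). Lipolysis (median log2 -0.31, adjusted p = 0.0495; adjusted p = 0.623 with an estimated correlation) had 0 of 10 passing, with 2 negative adjusted over the list alone. The lipolysis call was lost without replicate 2 of the VHL-negative DMSO libraries (adjusted p = 0.0521), replicate 1 or 3 of the VHL-negative JQ1 libraries (0.0767 and 0.0507), replicate 2 of the VHL-positive DMSO libraries (0.0547) or replicate 3 of the VHL-positive JQ1 libraries (0.0695). Without replicate 1 of the VHL-negative JQ1 libraries the medians were log2 -0.89 for ribosomal proteins, -0.72 for oxidative phosphorylation and -0.56 for NRF2 targets; without replicate 2 the last pair were -0.30 and -0.21. The replication median was log2 0.20 without replicate 2 of the VHL-positive DMSO libraries. With fry the adjusted p was 0.164 for ribosomal proteins and for oxidative phosphorylation, 0.277 for replication, 0.15 for fatty acid oxidation and NRF2 targets, and 0.0634 for cholesterol synthesis and the lysosome list. With protein-coding genes only, fatty acid oxidation (0.128), NRF2 targets (0.0878) and lipolysis (0.213) lost their calls, and NRF2 targets had 0.0614 without the first DMSO library of both lines. Lipolysis also lost its call with total counts alone (0.0608), a filter of 1 CPM (0.135), a replicate block (0.0538), without mitochondrial and structural RNA genes (0.052) and without the third JQ1 library of both lines (0.0943). Fatty acid synthesis (median log2 -0.32, adjusted p = 0.0559) and triglyceride synthesis (median log2 -0.26, adjusted p = 0.0774) missed the threshold of the list test. In some other settings they passed, with adjusted p from 0.000892 to 0.0484 and from 0.0132 to 0.0392. Neither passed with an estimated correlation.

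The authors' deposited comparison tables gave the same directions for the genes examined first. In them VHL changed by log2 1.60 (SE 0.121, adjusted p = 6.49e-37) in VHL-positive and 0.28 (adjusted p = 0.0911) in VHL-negative cells. MYC changed by log2 -0.08 (adjusted p = 0.851) and -1.13 (adjusted p = 8.49e-06), and HILPDA by log2 0.34 (adjusted p = 0.0937) and 2.32 (adjusted p = 3.09e-62). The authors' DESeq2 tables called 6454 genes in VHL-positive cells (3177 higher, 3277 lower) and 6504 in VHL-negative cells (2704 higher, 3800 lower). Of the edgeR calls 94.1 and 92.6% were also the authors' calls, and 0 had the opposite sign. A DESeq2 fit to the deposited counts gave the authors' fold changes again (Pearson's r = 1 over 18602 genes in each line). The authors' tables thus rest on the same counts and are no independent check.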

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

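Of the tests below, those on the scaling of the libraries, on a response of the endogenous gene shared with VHL-negative cells and on an equal chance of the middle position were chosen after the result was seen. The results listed here stood out because the change by JQ1 differed between VHL-negative and VHL-positive cells in edgeR's test of the difference with Benjamini-Hochberg adjustment. More negative in VHL-negative cells were LAMA1 (log2 -3.63), GDF15 (log2 -2.76), CALD1 (log2 -1.74), CP (log2 -1.67), CRISPLD2 (log2 -1.61), ATOH8 (log2 -1.61, adjusted p = 0.0452), CDKN1C (log2 -1.58, adjusted p = 0.0407), KRT7 (log2 -1.54, adjusted p = 0.044), TXNRD1 (log2 -1.37, adjusted p = 0.0325), MMP14 (log2 -1.31, adjusted p = 0.00152), VHL (log2 -1.29), FN1 (log2 -1.19, adjusted p = 0.0282), INSIG1 (log2 -1.06), LPIN1 (log2 -1.04, adjusted p = 0.00911) and CDKN1A (log2 -0.95, adjusted p = 0.022). More positive were FLG (log2 3.01), TGFB2 (log2 2.90, adjusted p = 0.00931), VGF (log2 2.13), NFIC (log2 2.03), HILPDA (log2 2.01), BAHCC1 (log2 1.96), CDT1 (log2 1.38, adjusted p = 0.0205) and CDH6 (log2 1.00, adjusted p = 0.0481). NFIC passed in only 1 of the 12 fits that left out 1 library. The difference was not examined with libraries left out for ATOH8, CDKN1C, KRT7, TXNRD1, MMP14, FN1, INSIG1, LPIN1, CDKN1A, TGFB2, CDT1 and CDH6. Their calls may be lost there, since the count of calls fell from 250 to 43 without replicate 3 of the JQ1-treated VHL-negative libraries. Lists with a difference were cholesterol synthesis (median log2 -0.60), ribosomal proteins (-0.58), oxidative phosphorylation (-0.48), fatty acid oxidation (-0.36), the lysosome list (-0.36), NRF2 targets (-0.35), lipolysis (-0.31) and DNA replication (0.43). With an estimated correlation these 8 calls were lost, with adjusted p from 0.623 to 0.676.

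For the difference, 2 of 100 splits of the 12 libraries, the real one included, gave as many genes as the real 250; the highest other gave 352, the next 36, and 81 gave none in edgeR. Splits that mix treatments raise the spread, which weakens this check. For the 4 comparisons of 2 groups, 10 splits are too few for a share under 0.05: 1 split, the real one, gave 6589, 6649, 6357 and 8479 genes, and the highest of the others gave 0.

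Ribosomal protein genes (mean log2 difference -0.52) and oxidative phosphorylation genes (-0.45) had a more negative JQ1 change in VHL-negative cells. Genes matched on exon length and abundance moved too, by a mean of -0.30 for the ribosomal list (SD 0.054 over 1000 draws). The list mean lay beyond these draws, which ignore correlation between genes. How closely the matched genes met the list in length and abundance was not measured. The test therefore cannot decide whether length and abundance are the whole cause or part of it. At the preset correlation the ribosomal list kept its call over the 12 fits leaving out 1 library, with a highest adjusted p of 7.9e-06. Since this p rests on the preset correlation, it argues against a single library for that test only. For JQ1 in VHL-negative cells the ribosomal call was lost without replicate 2 of the JQ1 libraries (median log2 -0.18, adjusted p = 0.116). The ribosomal mean of JQ1-treated VHL-negative libraries was 7.61, 6.77 and 7.2 log2 CPM in replicate order. In the same order these libraries held 2.92, 6.24 and 4.68% of counts in noncoding and pseudogene RNA and 0.458, 1.83 and 1.2% in NEAT1, so the ribosomal mean was lower where these were higher; JQ1-treated VHL-positive libraries held 2.45 to 2.76% in noncoding and pseudogene RNA. RNA composition is left open as a source of the difference, since 3 libraries are too few to separate it from the JQ1 response. Correlated genes within the list remain a candidate explanation, since the adjusted p was 0.623 with an estimated correlation. A biological difference between the lines was not tested apart from these.

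The VHL transcript rose with JQ1 in VHL-positive cells. Scaling was argued against by a smallest log2 fold change of 1.48 over the scaling alternatives. A rise of the chromosomal neighbourhood of the annotated gene was argued against by the highest change among 20 tested genes within 250 kb. This was log2 0.66 for EMC3 (edgeR adjusted p = 0.00218), less than VHL's own. The neighbourhood of the reintroduced copy was not covered. A response of the endogenous gene shared equally with VHL-negative cells was argued against by the difference between the lines (log2 -1.29, SE 0.173, adjusted p = 0.00161; 0.0694 without the third JQ1 library of both lines). A response of the reintroduced copy may remain, but the labels do not describe it and it was not tested.

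The third JQ1 library of each line lay between the first and the second in 76.6% (VHL-negative) and 52.9% (VHL-positive) of 11598 well counted genes. The lower of these, 52.9%, cannot decide whether each library had an equal chance of the middle position. The third VHL-positive DMSO library lay in the middle in 53.7% of genes, so such a share is not particular to JQ1 libraries. That comparison was added after these values were seen. A mixture of material from the first and second samples could not be decided either. Its residual lay -0.0245 from the log-scale one (bootstrap SE 0.018) over 11 genes in VHL-negative cells, and VHL-positive cells gave 0 usable genes.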

How the results depend on the processing

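The settings without the third JQ1 library of both lines, without the first DMSO library of both lines, with protein-coding genes only and with older symbols matched were chosen after seeing the data. For the 250 genes of the difference, no filter on low counts gave 1336, DESeq2 1283, adjusted p under 0.01 gave 47, and leaving out 1 library 43 to 3510; the cause was not tested. For JQ1 in VHL-positive cells, JQ1 in VHL-negative cells, and the lines under DMSO and under JQ1, adjusted p under 0.01 left 3989, 4039, 4137 and 5483 genes, and a change of at least 2-fold 2638, 2896, 3046 and 4137, both by construction. Leaving out 1 library gave 4710 to 5939, 4672 to 8106, 5008 to 6431 and 6395 to 9644, and 2737 to 3457 for the genes shared in direction. Without the third JQ1 library of both lines, with fewer samples, the counts were 4160 and 3957 for JQ1, 4814 for the lines under JQ1, 25 for the difference and 2083 shared. The histone list reversed for the difference without the first DMSO library of both lines (median log2 0.48, past the threshold; otherwise 0.12 with a falling test direction and adjusted p = 0.994); the cause was not tested. Of 399 results for named genes no called one changed sign, and 149 of 2430 called values no longer passed with 1 library left out. Uncalled MYC values did: log2 -0.08 became 0.16 for JQ1 in VHL-positive cells without replicate 2 of their DMSO libraries, and log2 -0.01 between the lines under JQ1 became 0.04 to 0.14 in 5 settings. All 46 list calls were lost with an estimated correlation. With total counts alone the median of all genes was log2 -0.14 for JQ1 in VHL-positive cells, 0.19 for the lines under JQ1 and 0.11 for the difference, against -0.03, 0.03 and 0.01 with TMM.

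A replicate block, pairing libraries by number, gave 6423, 6612, 6191, 8406 and 272 genes in the order of the comparisons and 3452 shared. The labels do not say that the numbers mark pairs, so the block stayed an alternative. After removal of group means, 6 of 12 libraries correlated best with their own number. Libraries of the same number correlated at 0.27, 0.33 and 0.0089 between DMSO and JQ1 in VHL-negative cells. The values were 0.014, -0.038 and 0.018 in VHL-positive cells, and 0.24, 0.17 and 0.012 between the JQ1 libraries of both lines. In the remaining pairs of groups they ran from -0.26 to 0.07, so pairing is left open. For the difference, 2-fold changes were recovered in 32.8% of simulated genes, which were drawn from genes with higher counts. Depth was not varied.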
